A study of Sus scrofa with 16 samples.

How the data were processed

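Ileum, the last part of the small intestine, was profiled in 16 female piglets, one array per piglet as the labels describe it. Per the labels' protocols, total RNA was extracted with the Chomczynski-Sacchi method, amplified as antisense RNA from an oligo(dT) primer, labelled with Cy5 and hybridised to one-colour CombiMatrix arrays. The day 5 piglets had been moved to another farm and assigned to the diets at random, per the labels. Priming at the poly(A) tail means that the signal depends on the 3′ end of each transcript. The scanner settings, the background correction, the between-array normalization and the gene content of the array are not given in the sources used here.

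The deposited values, one per probe and array, were read as log2 intensities made by the authors. The table holds 29767 rows for 16 arrays, with 0 missing values, given to the nearest 0.01. Values run from 5.65 to 15.99, just below 16, the log2 of the ceiling of a 16-bit scanner, which is the basis for reading them as log2. The array medians were 7.31 or 7.32, and in 15 of 16 arrays the sorted values lay within 0.05 log2 of the median array for 99% of ranks. The arrays therefore already shared one distribution, as after quantile normalization, and by the rule fixed beforehand the values were used as deposited. A normalization of this kind sets the overall level of every array equal, so a change of all transcripts in one direction cannot be seen. No background level or detection call accompanied the values, so which probes were above background is unknown. For arrays, the number of animals (4, 6 and 6) limits the precision.

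Rows are identified by a running number from 1 to 29767 and the table pairs none of these numbers with a gene, transcript or sequence. The gene tables provided list Ensembl and RefSeq identifiers, which share no column with these numbers, so 0 rows could be named. Probes are therefore given by number, and no position in the genome can be stated. A set of gene lists (digestive enzymes, transporters, mucus, immune cell markers and others) had been fixed before the data were examined. None of them could be tested. Whether a row is a single spot or an average of several is not given in the sources used here.

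Groups were taken from the source labels: weaning day (day 0, 28 days of age, n = 4), 5 days after weaning on the standard diet (33 days of age, n = 6) and 5 days after weaning on the diet with 5 g/kg sorbic acid (33 days of age, n = 6). Piglets are numbered within a group in the order of deposition, and these numbers pair nothing across groups. The labels give no litter, slide or hybridisation date. One linear model with the 3 groups was fitted per probe to all arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the variances (no intensity trend). A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all 29767 probes, two-sided, with no minimum change. The comparisons were standard diet day 5 against day 0, sorbic acid diet day 5 against day 0, sorbic acid against standard diet at day 5, and the mean of both day 5 groups against day 0. All changes are differences of log2 values. No filter on dim probes was applied. The test, the samples, the calling rule and most alternatives were set before the data were examined.

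The probes named were the 2 with the largest rise and the 2 with the largest fall among those called between standard diet day 5 and day 0, by the rule fixed for a table without gene names. Their values are given in the other comparisons too. Because both comparisons with day 0 use the same 4 arrays, their similarity was set against 100 simulated sets of unchanged groups, made by reassigning the arrays' deviations from their group means, and against estimates with the day 0 arrays split into 2 pairs.

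The fit was tested on simulated data built from the real probe means and spreads. With 200 of 29767 probes changed by 1 log2 between the diets, 95.5% were recovered; with a change of 0.5 log2, 53.0% were. For standard diet day 5 against day 0 the shares were 91.5% and 48.0%. The simulated noise was independent between probes, so it holds no arrays that deviate together. The changed probes were drawn from all levels, while the median within-group SD was 0.13 log2 in the lowest tertile of mean level and 0.24 log2 in the highest. The shares therefore do not give the recovery for bright probes or for arrays with shared deviations. Alternatives were quantile normalization, median centring, removal of the lowest tertile of probes by mean level, an intensity-trended robust prior, array weights, fits on the 2 groups compared, 1 surrogate variable (the iteratively reweighted algorithm of surrogate variable analysis, written out in R), stricter thresholds and leaving out each array. Fits without arrays that stood apart were added after the data had been seen.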

Results

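Gene expression in the ileum of 16 female piglets was measured on one-colour arrays of 29767 probes. Of these piglets, 4 were sampled on weaning day (day 0, at 28 days of age). The other 12 were weaned and sampled on day 5, at 33 days of age. Of these, 6 had received the standard diet and 6 a diet with 5 g/kg sorbic acid, a short unsaturated fatty acid used as a food preservative and feed acidifier, in place of barley flour. These 12 piglets were also moved to another farm at weaning, so the step from day 0 to day 5 joins weaning, transport and 5 days of age, which the design does not separate. The values are deposited intensities read as log2, with nearly the same distribution in each array, and probes carry numbers in place of gene names. Correlations between pairs of arrays lay between 0.902 and 0.987 across probes. Array numbers below identify piglets within a group.

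The first component of a principal component analysis held 29.5% of the variance and the second 20.0%. A straight line in this plane parts the 4 day 0 arrays from the 12 day 5 arrays, while the arrays of the 2 day 5 diets intermingled. The day 0 arrays did not form a compact group: day 0 array 3 lay nearer to day 5 standard array 2 than to any other day 0 array. Within groups, day 0 array 3 and day 5 standard arrays 2 and 5 lay at lower values of the first component than the other arrays of their groups. After subtraction of group means, the deviations of these 3 arrays were correlated across probes: r = 0.68 between day 0 array 3 and standard array 5, r = 0.34 between day 0 array 3 and standard array 2, and r = 0.45 between standard arrays 2 and 5. The 3 arrays were picked for their low values on the first component, which itself favours positive correlations among them. Probes are not independent replicates, so no p-value is attached to these correlations. Between arrays of different groups, leaving out only the pairs within this trio, the 82 such correlations ranged from -0.43 to 0.31, but those pairs were not picked in this way.

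**Figure D1:**
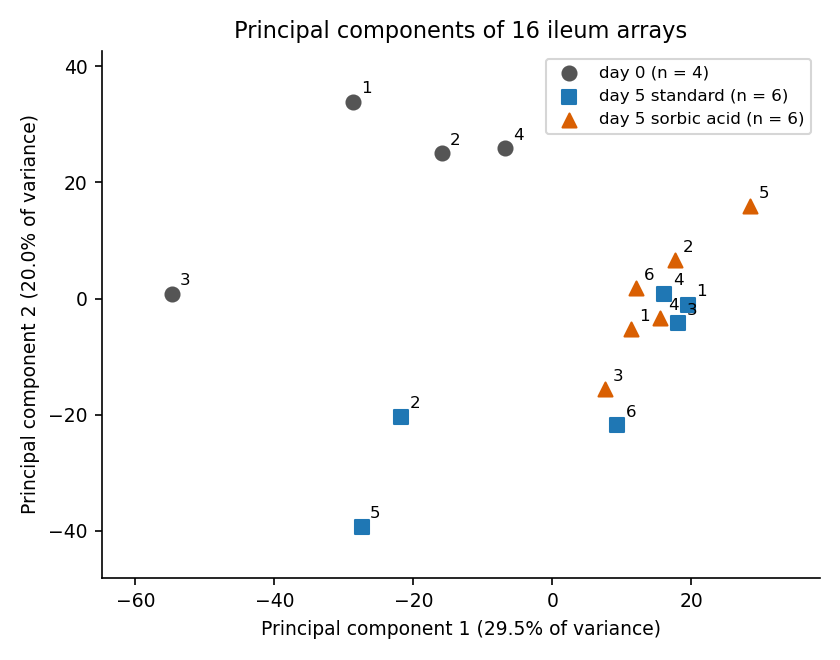
Scores of the 16 arrays on the first principal component (horizontal, 29.5% of variance) and the second (vertical, 20.0%), computed from the log2 values of all 29767 probes; each point is one piglet, numbered within its group. A straight line parts the 4 day 0 arrays from the 12 day 5 arrays, but day 0 array 3 lies nearer to standard array 2 than to other day 0 arrays. The 2 day 5 diets overlap, and day 0 array 3 and standard arrays 2 and 5 lie to the left of their groups.

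The change across weaning on the standard diet was measured by comparing day 5 standard (n = 6) with day 0 (n = 4). A total of 2515 probes, 8.45% of those tested, were called at an adjusted p under 0.05 with limma's moderated test: 1683 rose after weaning and 832 fell. The rises were larger, with a median of 0.61 log2 against -0.43 log2 among the falls. Changes of at least 2-fold were seen at 225 called probes, of which 206 rose and 19 fell. Calls were more frequent among bright probes: 14.9% of the highest tertile of mean level (7.82 log2 or more), 9.21% of the middle tertile and 1.28% of the lowest were called. The median change over all probes was -0.02 log2. The split by direction depended on single arrays: without day 0 array 1 there were 997 rises and 405 falls, without day 0 array 2 there were 404 falls and without standard array 6 there were 517, while array weights gave 1513 falls, 1 surrogate variable 1750 and a fit on these 2 groups alone 476.

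Probe 24700 had the largest called rise. Its level went from 10.98 ± 1.35 (SD, n = 4) on day 0 to 13.68 ± 0.71 (SD, n = 6) on the standard diet at day 5, a change of 2.70 log2 (SE 0.49) or 6.51-fold, with a limma adjusted p of 0.00252. Probe 3016 rose from 10.11 ± 0.66 to 12.27 ± 0.85, by 2.16 log2 (SE 0.36) or 4.46-fold, with an adjusted p of 0.0012. Probe 2356 had the largest called fall, from 14.38 ± 0.67 on day 0 to 11.91 ± 0.96, a change of -2.47 log2 (SE 0.52) with an adjusted p of 0.00665. Probe 16545 fell from 10.62 ± 0.95 to 8.89 ± 0.53, a change of -1.73 log2 (SE 0.40) with an adjusted p of 0.012. For each of these 4 probes the ranges of the day 0 arrays and of all 12 day 5 arrays overlapped. For probe 2356 the overlap came only from sorbic acid array 5, at 14.78. Its standard diet arrays reached 13.09 at most, below the lowest day 0 array at 13.54. The call of probe 16545 was lost without day 0 array 3 and standard arrays 2 and 5, at -1.54 log2 and an adjusted p of 0.0789. It returned when sorbic acid array 5 was left out as well, at the same change and a limma adjusted p of 0.0427. The calls of the other 3 remained.

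**Figure D2:**
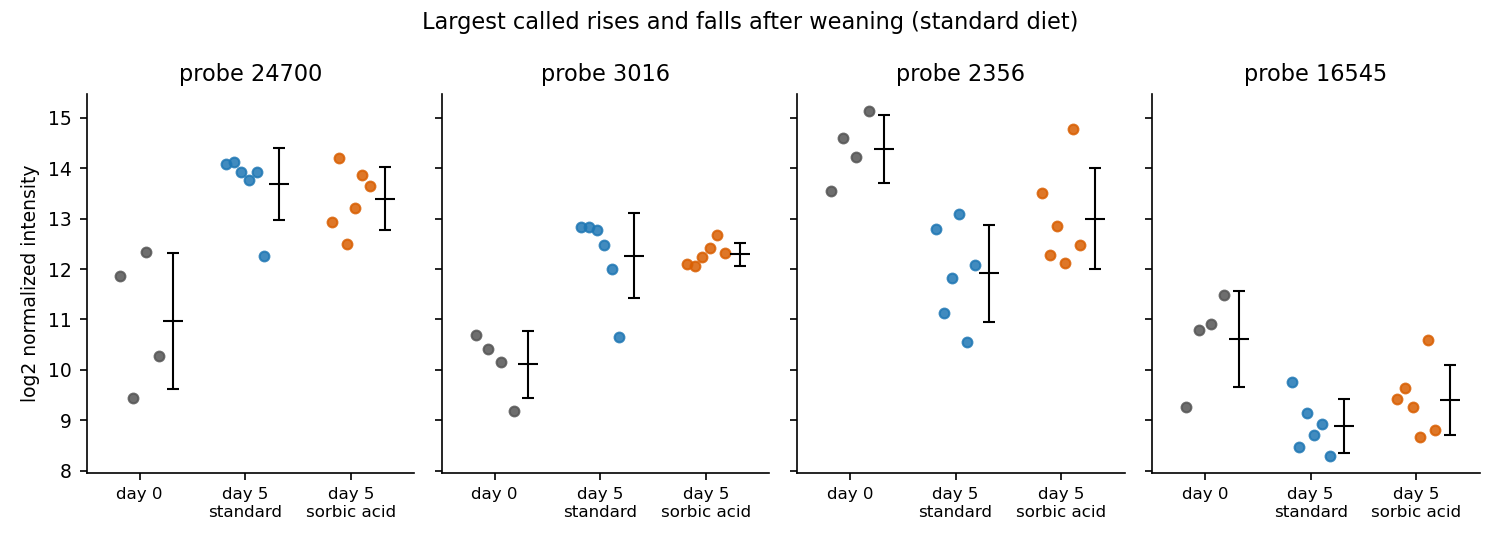
Log2 normalized intensity (vertical axis) of the 2 probes with the largest called rises and the 2 with the largest called falls between day 0 and day 5 on the standard diet, in each of the 16 piglets; points are piglets, the horizontal dash is the group mean and the bar its SD (n = 4, 6 and 6). Probes 24700 and 3016 are higher and probes 2356 and 16545 lower at day 5 on the standard diet. Each shows some overlap between day 0 and day 5 arrays, for probe 2356 only through sorbic acid array 5.

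The same interval was compared in piglets that received sorbic acid (n = 6) with the same 4 day 0 piglets. Here 2795 probes, 9.39%, were called, of which 1552 rose and 1243 fell. The median rise was 0.58 log2 and the median fall -0.50 log2, and 201 called probes changed at least 2-fold, 178 upward and 23 downward. Probe 24700 rose by 2.42 log2 (SE 0.49, limma adjusted p = 0.00561) and probe 3016 by 2.19 log2 (SE 0.36, adjusted p = 0.00138). Probes 2356 and 16545 did not pass here, at -1.38 log2 (SE 0.52, adjusted p = 0.109) and -1.21 log2 (SE 0.40, adjusted p = 0.0669). Both passed without sorbic acid array 5, at -1.74 log2 (adjusted p = 0.0228) and -1.45 log2 (adjusted p = 0.0202), and probe 16545 also without day 0 array 1, at -1.67 log2 (adjusted p = 0.0141). With array weights both passed too, at -1.90 log2 (adjusted p = 0.00648) and -1.60 log2 (adjusted p = 0.00649). Probe 2356 also passed with 1 surrogate variable, at -2.06 log2 (adjusted p = 0.0131). Each of these probes passed in only 4 of 25 alternative fits. The number of calls depended on the day 0 arrays: it was 1693 (890 rises and 803 falls) without day 0 array 1 and 1774 (711 falls) without day 0 array 3, and the falls numbered 725 without day 0 array 2. With array weights there were 4459 calls (2249 rises and 2210 falls), and with 1 surrogate variable 2187 (1419 rises and 768 falls). The standard diet comparison fell to 1402 calls without day 0 array 1.

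Averaged over both diets, the 12 day 5 piglets differed from the 4 day 0 piglets at 3633 probes, 12.2% of those tested, of which 2079 rose and 1554 fell. Without day 0 array 1 this count was 2070 (1217 rises and 853 falls), and the falls numbered 859 without day 0 array 2 and 945 without day 0 array 3. At least 2-fold changes were called at 211 probes, 192 upward and 19 downward. In this comparison all 4 named probes were called, at 2.56 log2 for probe 24700 (limma adjusted p = 0.00117), 2.17 log2 for probe 3016 (adjusted p = 0.000343), -1.92 log2 for probe 2356 (adjusted p = 0.0117) and -1.47 log2 for probe 16545 (adjusted p = 0.0122).

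The effect of sorbic acid itself was measured by comparing the 2 diets at day 5, with 6 piglets on each. No probe was called: 0 of 29767 passed, and the lowest adjusted p by limma's moderated test was 0.868. Before adjustment, 1313 probes had p under 0.05, where 1488 would be found by chance. The count of calls was also 0 in all 25 alternative fits, with array weights and with 1 surrogate variable among them. Several of these could change little: leaving out a day 0 array keeps the diet estimates, and renormalization acts on arrays that already share one distribution. The surrogate variable ran from -0.31 to -0.02 on sorbic acid and from -0.18 to 0.51 on the standard diet, so it may take up part of a diet difference. At the 4 named probes the difference between sorbic acid and standard diet was -0.29 log2 (95% interval -1.22 to 0.65) for probe 24700, 0.03 log2 (-0.64 to 0.71) for probe 3016, 1.09 log2 (0.11 to 2.07, limma adjusted p = 0.868) for probe 2356 and 0.52 log2 (-0.24 to 1.27) for probe 16545. These probes were chosen for extreme values in the same standard diet arrays, which pushes the diet difference up for probes that fell and down for those that rose, so the intervals are not unbiased estimates of a diet effect. Over the 25 alternative fits the estimates ranged from -0.57 (without standard array 6) to -0.06 log2 (with 1 surrogate variable) for probe 24700, from -0.29 (without standard array 6) to 0.15 log2 for probe 3016, from 0.20 (without 4 arrays, sorbic acid array 5 among them) to 1.32 log2 for probe 2356, and from 0.07 (with array weights) to 0.69 log2 for probe 16545.

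The intervals, computed per probe without adjustment for their number, bound the size of diet differences that these arrays leave open. For 99.2% of all probes the 95% interval of the diet difference lay within 2-fold in either direction, and for 92.4% it lay within 1.5-fold. Among the 3633 probes called between day 5 and day 0, these shares were 99.6% and 93.2%. Over all probes the median absolute change with weaning was 0.12 log2 and the median absolute diet difference 0.08 log2, with a median half-width of the diet interval of 0.21 log2. At the 3633 probes, whose choice by their weaning change enlarges that change, these medians were 0.47, 0.09 and 0.23 log2. The intervals were wider for bright probes: in the highest tertile of mean level, 97.7% lay within 2-fold and 81.1% within 1.5-fold. Estimates of 1 log2 or more between diets were seen at 4 probes, none of which passed the test.

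**Figure D3:**
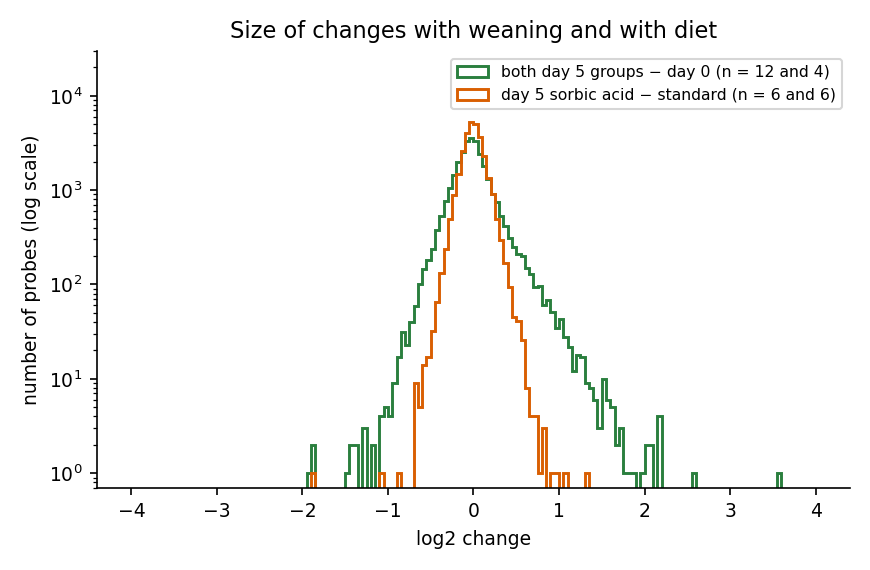
Number of probes (vertical, log scale) by log2 change in bins of 0.05 (horizontal), for the mean of both day 5 groups minus day 0 (n = 12 and 4) and for sorbic acid minus standard diet at day 5 (n = 6 and 6). The weaning distribution is wider (SD 0.27 log2) than the diet distribution (SD 0.14 log2) and has a longer tail of rises than of falls.

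The changes since weaning day were then set side by side for the 2 diets. Of the probes that rose on the standard diet, 1244 (73.9%) were also called as rises on the sorbic acid diet, where independent lists of these lengths, with no controls in common, would share 87.7. Of those that fell, 547 (65.7%) were called as falls on both diets, where independent lists would share 34.7. No probe was called in opposite directions, and all but 1 of the 2515 probes called on the standard diet changed in the same direction on the sorbic acid diet. The shared day 0 arrays raise such overlaps: over all probes 80.7% had the same sign on both diets, while unchanged groups against shared controls gave 71.3% on average and up to 86.3%, and split day 0 arrays gave 64.9%. Across probes, which are not independent replicates, the log2 changes on the 2 diets had a Pearson correlation of 0.87. In 100 simulated sets of unchanged groups with shared day 0 arrays the mean was 0.60, with a range from -0.12 to 0.90. The observed correlation is inside this range. The deviations of whole arrays were reassigned, so the sets also carry the arrays that deviate together. The width of the range can therefore not be credited to the shared day 0 arrays alone. With the day 0 arrays split, 2 for each diet, the correlation over the 6 arrangements averaged 0.60 and ranged from 0.43 to 0.79. The covariance of the changes was 0.0665, against a mean of 0.0146 and a highest value of 0.0511 in the simulated sets. The difference of 0.0519 was close to the mean covariance of 0.0527 with split day 0 arrays, whose range was 0.0418 to 0.0628. Both values remove an estimate of the error of the shared reference from the same covariance, so their closeness is not independent support.

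**Figure D4:**
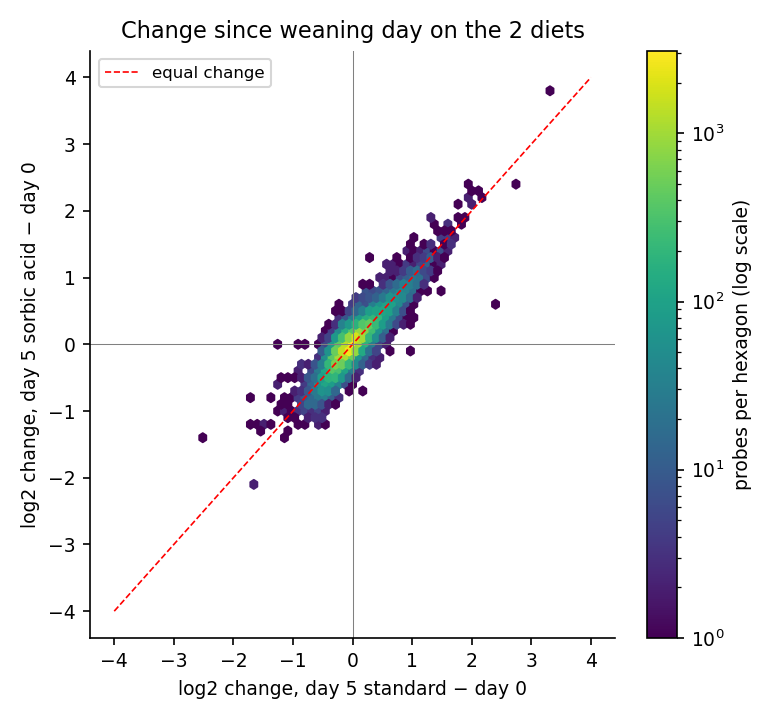
Log2 change of each of the 29767 probes from day 0 to day 5 on the standard diet (horizontal) and on the sorbic acid diet (vertical), as hexagons coloured by the number of probes on a log scale; the dashed line marks equal change. Probes lie along the line (Pearson r = 0.87), part of which comes from the 4 day 0 arrays that both axes share.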

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

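The checks for outlying arrays covered 21 sets of values, namely the 4 named probes and 3 measures per array in each of the 3 groups, and about 1.05 sets would be marked by chance. A single one was. The level of probe 24700 in day 5 standard array 6 was 12.25, while the other 5 arrays of that group lay between 13.77 and 14.12. The same array came close to being marked at probe 3016, at 10.66 where the other 5 lay between 12.01 and 12.84. There its gap to the nearest array was 0.619 of the group's range, with a limit of 0.625. At both probes its level was below the highest day 0 level, 12.33 for probe 24700 and 10.69 for probe 3016. Leaving standard array 6 out does not end the call of probe 24700. Over the 16 fits that each left out one array, its limma adjusted p stayed between 0.0012 and 0.0104 on the standard diet against day 0. On sorbic acid against day 0 it stayed between 0.0032 and 0.0229.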

How the results depend on the processing

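The fits without day 0 array 3 and standard arrays 2 and 5, alone or with sorbic acid array 5, were chosen after the data were seen. The diet comparison called 0 probes in all 25 alternative fits (the 2 stricter rules could give nothing else). Fits that leave out a day 0 array keep its estimates and are weak checks of it. At p under 0.05 before adjustment it held 1590 probes with array weights, 1257 with the trended robust prior, 719 with 1 surrogate variable and 684 without day 0 array 3 and standard arrays 2 and 5. Quantile normalization, median centring, removal of the lowest tertile of probes by mean level, and the trended robust prior each kept the counts of the 3 weaning comparisons within 1.5 times, as did fits on only the groups compared for each diet (not run for both day 5 groups). Because the arrays already shared one distribution, quantile normalization and median centring could change little and say little about stability. The processing before deposition was not varied. Leaving out one array at a time gave 1402 (without day 0 array 1) to 2820 (without day 0 array 4) calls on the standard diet, 1693 (without day 0 array 1; 1774 without day 0 array 3) to 3237 on sorbic acid, 2070 (without day 0 array 1) to 4083 for both day 5 groups, and 0 between diets, with correlations of the changes from 0.83 to 0.91. With array weights the sorbic acid comparison gave 4459 calls, and with 1 surrogate variable the standard diet comparison gave 4079; the causes were not tested. Falls on sorbic acid numbered 2210 with array weights and 768 with the surrogate variable, and for both day 5 groups 2388 with array weights. At least 2-fold changes numbered 225, 201 and 211 (standard, sorbic acid, both), and an adjusted p under 0.01 left 1025, 1080 and 1600, by construction of a stricter rule. Rises made up 66.9% of standard diet and 55.5% of sorbic acid calls, 56.7% and 50.4% with array weights, and 57.1% and 64.9% with the surrogate variable, which turned the order of the diets. Splitting the day 0 arrays lowered the correlation to 0.60, a setting that removes their shared error and leaves 2 per diet. Of 2515 standard diet calls, 2368 remained with array weights and 1742 without day 0 array 3 and standard arrays 2 and 5, which called 2453; of 2795 sorbic acid calls, 2711 remained with array weights, 1677 with the surrogate variable and 2000 without those 3. Without those 3 and sorbic acid array 5, the standard diet comparison called 2978. Probes 24700 and 3016 were called in both weaning comparisons under every fit run; probe 2356 passed on sorbic acid in 4 of 25 alternatives (adjusted p from 0.00648 to 0.216 over all 25) and probe 16545 in 4 of 25 (0.00649 to 0.18), both of them with array weights and without sorbic acid array 5. The gene list tests and the averaging of probes per gene were not run, because no probe could be named. Without background values, the share of probes below detection is unknown. No paired analysis was possible because the labels give no replicate numbers shared between groups.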

Other observations

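The tests chosen only after the results they bear on had been seen were those of wrong day labels, of signal level, of the diet difference in the score and in the gap between probe blocks, and of the share of rises without 3 arrays.

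The weaning response was summarised per piglet to compare its size between the diets. A score was formed as the mean of the 2079 probes that rose minus the mean of the 1554 that fell between both day 5 groups and day 0, a choice of probes that weights the 2 diets equally. It was -0.87 ± 0.15 (SD, n = 4) on day 0, 0.17 ± 0.14 (SD, n = 6) on the standard diet and 0.19 ± 0.05 (SD, n = 6) on sorbic acid. That sorbic acid may change the size of the response was tested as a hypothesis: the difference between diets was 0.02 log2 (95% interval -0.11 to 0.16), with a two-sided exact permutation p of 0.753 over 924 arrangements. Without standard arrays 2 and 5 the direction turned, at -0.05 log2 (exact permutation p = 0.3). These arrays had been picked for low values of the first component, where the day 0 arrays also lay. Standard array 2 had the lowest score of the day 5 arrays, at -0.07. Leaving them out therefore favours a higher standard diet mean, and the turn is not a separate result. The change from day 0 to the standard diet was 1.04 log2, enlarged by the choice of probes for that change. The median SD per probe was 0.17 log2 in the standard group and 0.14 log2 on sorbic acid, and 0.14 log2 in the standard group without its arrays 2 and 5.

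Other splits of the arrays bear on whether chance can give the counts. For the standard diet comparison, 1 of 100 splits, the real one, gave 2515 or more calls; the highest of the others gave 433, in a split that put all 4 day 0 arrays in the group of 6. The next gave 407, in a split that mixed the days but set day 0 array 3 and standard arrays 2 and 5 together with standard array 4, which points to a structure of the arrays apart from the day; with day 0 array 2 or day 0 array 4 in place of standard array 4 the counts were 15 and 0. For sorbic acid against day 0, 1 of 100 splits reached 2795, and the highest other gave 28. For both day 5 groups, 1 of 100 reached 3633, with 8 in the highest other. Chance is therefore excluded at a share of 0.05 for these 3 counts. Between the diets the real split called 0 probes by limma and the highest other 8; since each of the 100 splits must give at least 0, that count decides nothing. Before adjustment, 47 of 100 splits gave at least the 1313 probes at p under 0.05 of the real one, with 4723 in the highest other, so chance is not excluded for that count.

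Day 0 array 3 and standard arrays 2 and 5, picked by their low first component, deviated together from their groups, across 2 days. A wrong day label was tested on a score from probes chosen without these arrays, set to 0 at the other day 0 arrays and 1 at the other day 5 arrays: standard array 5 lay at 0.894, day 0 array 3 at -0.0025, and standard array 2 at 0.622, where the other day 0 arrays reached 0.115 and the other day 5 arrays began at 0.920. The other arrays also chose the probes and set the scale, so arrays left out are expected to fall inward of them. The position of standard array 5 just below the other day 5 arrays is therefore not read as a deficit. Standard arrays 2 and 5 lay far above the other day 0 arrays, and day 0 array 3 lay among those. These positions argue against a wrong day label for each of the 3. Mean signal level accounted for 0.52% of the variance of the shared deviation. Because the arrays already shared one distribution, most of a level-dependent bias would be absent from these values. This share therefore cannot exclude such a bias before normalization. The difference between blocks of probe numbers described next accounted for 0.791%, so it is not the main source. A hybridisation batch, a shared litter or a difference in the piece of ileum sampled may remain, and no value here separates them, since the labels give none of them and no probe can be assigned to a cell type; no biological explanation was tested.

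Signal depended on the probe number. The probes were cut into 2 blocks after probe 8273, where the cumulative sum of mean level about its average reached its extreme. This rule gives a cut even for a gradual change along the numbers. The 8273 lower-numbered probes averaged 8.04 log2 and the 21494 higher-numbered ones 7.45 log2, and 11.2% against 7.41% of them were called on the standard diet. The gap between the blocks within an array was 0.60 ± 0.03 log2 (SD, n = 4) on day 0, 0.61 ± 0.04 (SD, n = 6) on the standard diet and 0.56 ± 0.04 (SD, n = 6) on sorbic acid, a diet difference of -0.05 log2 with a two-sided exact permutation p of 0.0498, or 0.0996 after adjustment over the 2 measures per array tested between diets. The probes were cut by mean level into 8 bins of similar numbers of probes. The diet change of the lower-numbered block lay below that of the other in 8 of 8 bins. Level between bins is therefore not the whole source, but blocks may still differ in level within a bin. The bins come from the same arrays, so they are not independent results. The difference depended on level, from -0.02 log2 in the dimmest bin to -0.10 log2 in the brightest. Without standard arrays 2 and 5 the difference was -0.03 log2 (exact permutation p = 0.233), so an effect of the diet and a contribution of those 2 arrays cannot be told apart with so few arrays. Whether the level changes at a single point or gradually along the numbers was not tested, nor was the cause.

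Rises formed 66.9% of the calls on the standard diet and 55.5% on sorbic acid, a difference of 11.4 percentage points. Of 100 splits of the 12 day 5 arrays into groups of 6, 37 gave a difference as large, up to 16.6 points, so chance assignment of piglets is not excluded. Without day 0 array 3 and standard arrays 2 and 5 the shares were 59.5% and 57.1%, a difference of 2.34 points, so those arrays may contribute. The order of the diets also depended on the setting: it turned with 1 surrogate variable (57.1% and 64.9%) and without the 3 arrays and sorbic acid array 5 (58.6% and 60.1%), and kept its direction with array weights (56.7% and 50.4%) and at an adjusted p under 0.01 (82.5% and 65.2%).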
